A study of Mus musculus with 160 samples.

How the data were processed

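Gene expression was measured by RNA sequencing in 160 libraries from 35 male mice of 4 inbred strains, C57BL/6J, A/J, DBA/2J and SJL. The mice were moved from chow at 12 weeks of age to a mouse version of an American, Mediterranean, vegetarian or vegan diet, which per the labels had the same energy and macronutrients from different sources. After 6 weeks on the diet, at 18 weeks of age, liver, quadriceps muscle, brown fat, subcutaneous fat and visceral fat were taken. Each of the 16 combinations of strain and diet had 2 libraries per tissue, so that each tissue had 32. Most mice gave all tissues, and mouse numbers in the text are those of the labels.

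Per the labels, frozen tissue was pulverised, RNA was extracted with TRIzol and RNeasy Micro columns, and stranded libraries from polyadenylated RNA were sequenced as paired reads on a NovaSeq6000. The authors checked reads with FastQC, trimmed them with Trim Galore, aligned them to GRCm39 with HISAT2 and counted them per Ensembl gene with HTSeq. The mismatch penalty of the aligner was relaxed for strains other than C57BL/6J, so every comparison of strains is also a comparison of alignment settings and of distance from the reference genome. Tool versions, the annotation release and the strand setting are not given in the sources used here. The authors deposited estimated counts made with HTSeq, in which a read with several positions was shared fractionally among them: 74.4% of the non-zero values were whole within 1e-06. Values of genes with near-identical copies are therefore uncertain. The authors' deposited TPM table was used for 1 alternative. How its gene lengths were taken is not given. Of 56980 gene identifiers, 56236 had a name and position in GENCODE vM39 for GRCm39.

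Counts were rounded and analysed per tissue with edgeR 4.0.16 in R 4.3.3. Genes were kept with filterByExpr on the 16 cells (minimum count 10, minimum total 15), library sizes were scaled by TMM, and quasi-likelihood F-tests were run with robust dispersion. A model with strain and diet as additive terms gave the test over all diets, each diet against American, the test over all strains, and each strain against the mean of the other 3. A model with all 16 cells gave the strain by diet interaction and the diet test within each strain. P values were adjusted by Benjamini-Hochberg within each test, and genes under 0.05 were called. The 3 diet contrasts share the American libraries and are not independent. Visceral and subcutaneous fat were compared over 64 libraries with strain and diet in the model. Levels are CPM (counts over library totals), given as mean ± SD. They are scaled by TMM, except the tissue markers and shares of liver, muscle or brown fat transcripts and the Cd79a levels that are called unscaled, which are over plain library totals. Log2 differences come from edgeR and carry their standard error (SE). Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.

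The groups, tests, gene lists, alternatives first listed and the rule for named genes were fixed before the data were examined. The rule took genes with a mean of at least 5 CPM and an assigned symbol: per diet contrast the 2 largest rises and 2 largest falls with 1 sign in all 4 strains, per strain and tissue the largest rise and fall, the 4 smallest p of an interaction, and the 10 largest rises and falls between depots. It also took up to 4 members with the smallest adjusted p of each list described, all known strain variants and the genes of tissue identity. The other genes named in the text were chosen after their values were seen. The 40 lists of pathway and cell type genes were tested with camera from limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, again with an estimated correlation, and with fry; lists with at least 5 tested members were used, and list medians are on this scale.

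The alternatives were RLE size factors, no filter, DESeq2 1.42.0, limma on log2 of TPM plus 1 for genes with a mean of at least 1 TPM, the 16-cell model averaged over strains, each strain's 8 libraries alone, each library left out in turn, and the mouse as a block for the 2 fat depots. After the data were seen, more were added: Alb, Ckm and Ucp1 as covariates of tissues other than their own, Cd79a as a covariate in brown fat, and fits without libraries holding over 4 times the brown fat median of Cd79a. A last added fit left out libraries with over 10% of the liver level of Alb, over 10% of the liver genes of another strain, or under 10% of the depot's median of Wt1 (visceral) or Hoxc10 (subcutaneous). More than 1 version of that definition was tried. Where this removed both libraries of a cell, the interaction and the diet tests within strains were run over the cells left. The lists were also tested with the covariates and without these libraries, in brown fat also with Cd79a as a covariate and without the 3 libraries high in it. The lists were then tested between the depots, and the depots without the visceral library of mouse 50 or 39. Each library's content of another strain was read from genes with at least 2 CPM in the liver of that strain and at most 5% of it in the library's own strain. Groups were also reassigned 100 times within the other factor, and the depots 60 times within mice. Known changes added to simulated data were used to test the recovery of each test.

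Library totals ran from 18.0 to 54.8 M counts. Between the 80 pairs of libraries of 1 group the spread exceeded counting error in every pair, with a chi-squared per degree of freedom of at least 10.7 and a median of 62. Separate animals differ by more than counting error in general, so this does not show what limits the precision.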

Results

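The counts came from 5 tissues of male mice of 4 inbred strains fed 1 of 4 diets. Each tissue had 32 libraries, 8 per strain and 8 per diet, with 2 mice per strain and diet. Library totals, in M counts, ranged from 18.0 to 28.3 M in brown fat, 18.6 to 29.9 M in liver, 20.0 to 30.4 M in muscle, 18.9 to 38.7 M in subcutaneous fat and 20.5 to 54.8 M in visceral fat. The tissues carried the genes known to mark them, given here and in the next paragraph as CPM without TMM scaling. Alb, the main plasma protein made by hepatocytes, stood at 85100 ± 21100 CPM in liver (SD, n = 32), and Ckm, the muscle creatine kinase, at 13900 ± 2830 CPM in muscle. Ucp1, which uncouples respiration to make heat, reached 7000 ± 1940 CPM in brown fat. The fat hormone genes Adipoq and Lep stood at 2210 ± 886 and 1880 ± 890 CPM in visceral fat. Wt1, a transcription factor of the lining of the body cavity, was at 14.3 ± 4.85 CPM in visceral fat against 0.204 ± 0.354 CPM in subcutaneous fat.

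Liver transcripts also appeared in the other tissues, unevenly. Alb exceeded 10% of the liver mean in 4 of 32 brown fat libraries, 8 of 32 muscle libraries, 4 of 32 subcutaneous and 8 of 32 visceral libraries, with maxima of 21.4%, 42.8%, 54.4% and 62.2%. Liver genes that the library's own strain hardly expresses, but another strain does, reached over 10% of their level in 3, 4, 2 and 9 of these libraries. The highest shares were 55.4% and 52.7%, for DBA/2J liver genes in the visceral libraries of the C57BL/6J vegan mice 13 and 16. In the 32 liver libraries the same measure stayed at or under 8.36%. In the visceral library of SJL mouse 50, on the American diet, Wt1 was 0 CPM, while Hoxc10, a homeobox gene of the lower trunk, was 16.3 CPM, near the subcutaneous mean of 16.1 ± 6.16 CPM. In the subcutaneous library of A/J mouse 24 Hoxc10 was 0.291 CPM. Counts of genes are given below with all libraries, and without these 5 brown, 9 muscle, 5 subcutaneous and 12 visceral libraries where that moves them. Ckm was 26.5% of the muscle level in visceral mouse 2 and 21.4% in subcutaneous mouse 25. Ucp1 was 42.6% of the brown fat level in visceral mouse 24. No library was left out for Ckm or Ucp1.

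**Figure D1:**
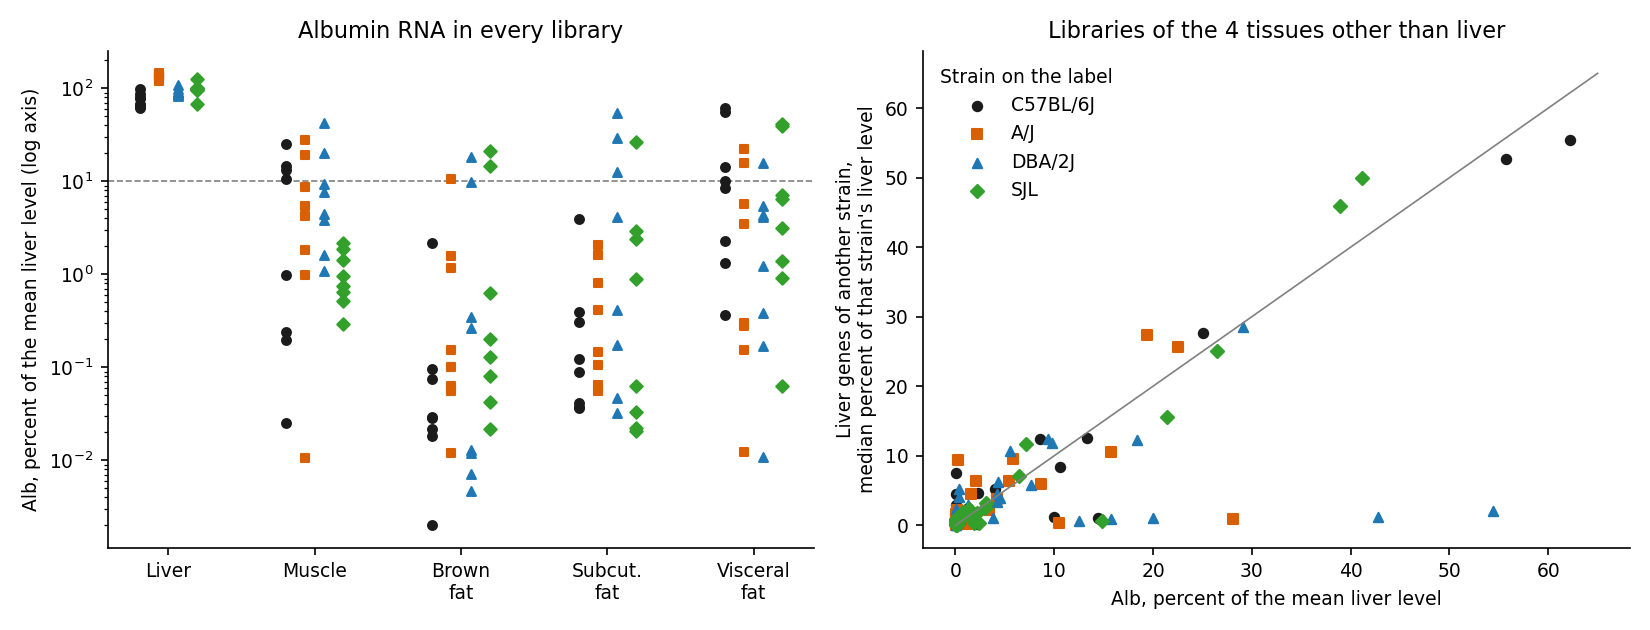
Alb in percent of the liver mean (horizontal axis) against the level of liver genes of another strain in percent (vertical axis) for each library of the 4 tissues other than liver. The visceral libraries of C57BL/6J mice 13 and 16 sit at 62.2% and 55.7% of Alb.

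The diets were first compared in liver. On the Mediterranean diet Ucp2, a mitochondrial carrier related to Ucp1, rose from 28.5 ± 6.92 to 49.7 ± 16.7 CPM (SD, n = 8 each), a log2 change of 0.79 (SE 0.133, adjusted p = 0.0267). Gpx3, a secreted glutathione peroxidase, rose from 4.68 ± 1.36 to 8.13 ± 3.66 CPM (log2 0.77, SE 0.152, adjusted p = 0.0364). Fmn2, an actin nucleator, fell from 9.04 ± 5.96 to 4.61 ± 3.02 CPM (log2 -1.03, SE 0.184, adjusted p = 0.0352). Stap1, a signalling adaptor of immune cells, fell from 9.06 ± 12.0 to 4.16 ± 5.82 CPM (log2 -1.18, SE 0.252, adjusted p = 0.0492). All 4 moved in the same direction in 4 of 4 strains, which the rule for naming genes required. Of 18636 genes, 27 were called against American, 21 higher and 6 lower. Macrophage genes were higher as a group: 18 of 20 had higher means, with a median log2 difference of 0.38 (camera adjusted p = 8.84e-09, adjusted p = 0.622 with an estimated correlation). Of these 3 passed the test over all genes and 9 when adjusted over the list alone. C1qb, a chain of the first complement component, rose from 42.3 ± 10.8 to 69.3 ± 25.7 CPM (log2 0.68, SE 0.139, adjusted p = 0.0364). Csf1r, the receptor for the macrophage growth factor, rose from 53.0 ± 13.7 to 91.7 ± 35.6 CPM (log2 0.76, SE 0.155, adjusted p = 0.0364), and C1qa reached adjusted p = 0.0499. In the group for antigen presentation by MHC class II 9 of 10 genes were higher, with a median log2 difference of 0.83 (camera adjusted p = 5.2e-07, adjusted p = 0.672 with an estimated correlation). Ctss, a lysosomal protease, was the 1 member past the test, at 32.3 ± 5.63 against 49.6 ± 17.9 CPM (adjusted p = 0.0492), while 9 passed when adjusted over the list alone. Without the count filter 6 genes were called, and the adjusted p of Stap1, C1qb, Csf1r, C1qa and Ctss was 0.0729, 0.0639, 0.0729, 0.0729 and 0.0722. The count ran from 0 without A/J mouse 18 (American) to 142 without DBA/2J mouse 39 (Mediterranean), and 21 of the 32 libraries each moved it by over 1.5 times when left out. DESeq2 called 199 genes, limma on TPM 0 and the averaged 16-cell model 95.

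**Figure D2:**
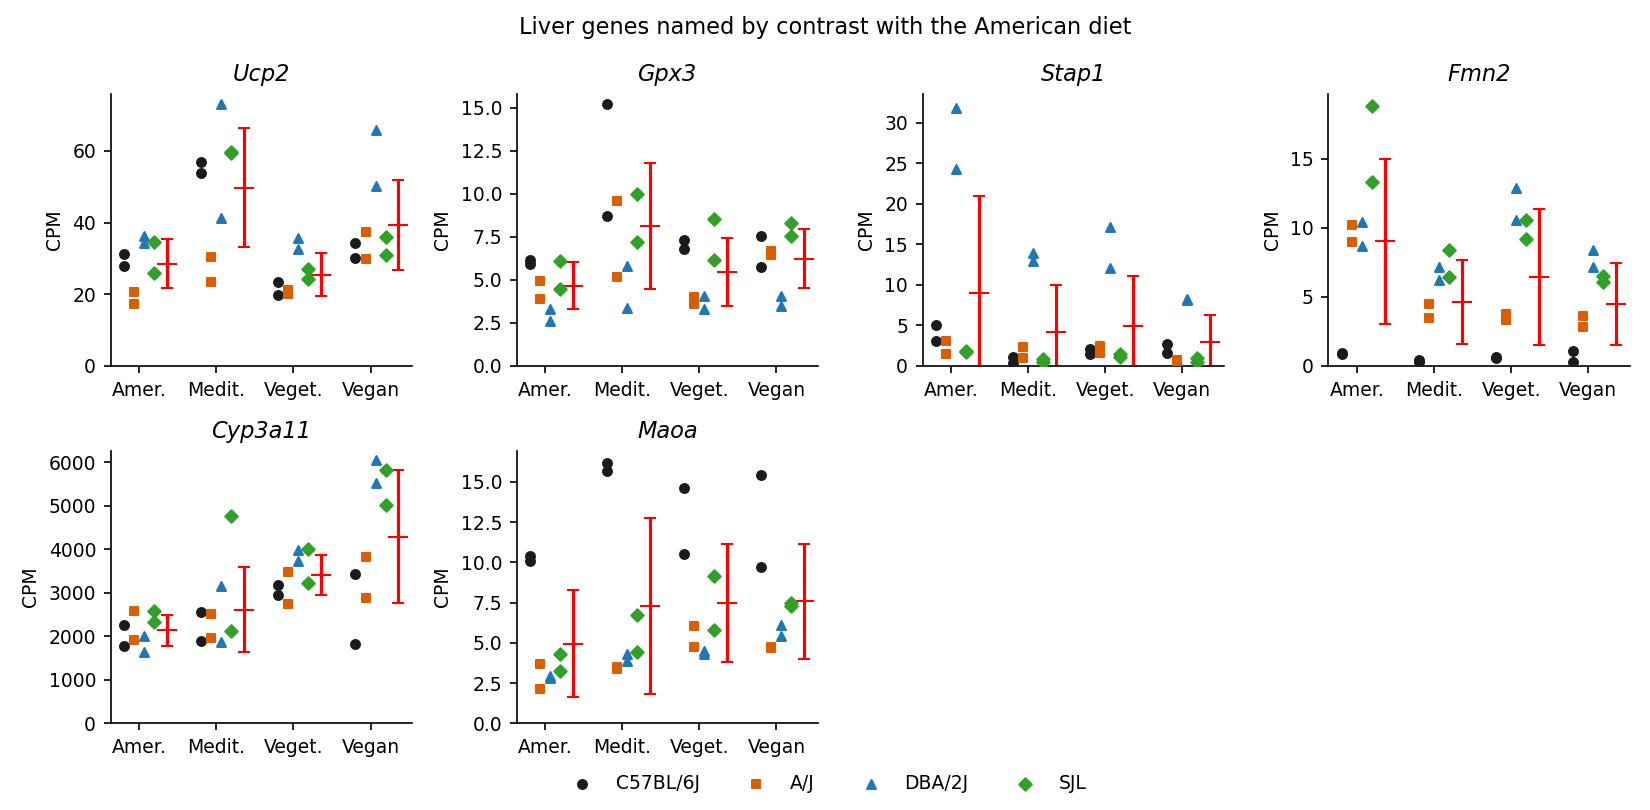
Liver CPM (vertical axis, linear scale) of 6 genes by diet (horizontal axis), with 1 point per mouse coloured by strain and bars at the mean ± SD of 8 mice. Cyp3a11 stood at 2130 ± 355 CPM on the American and 4290 ± 1530 CPM on the vegan diet.

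On the vegan diet Cyp3a11, a cytochrome that clears drugs and bile acids, rose in liver from 2130 ± 355 to 4290 ± 1530 CPM (SD, n = 8 each), a log2 change of 0.95 (SE 0.172, adjusted p = 0.0146). Maoa, which breaks down monoamines, rose from 4.96 ± 3.34 to 7.59 ± 3.56 CPM (log2 0.72, SE 0.146, adjusted p = 0.0326). Stap1 fell to 2.95 ± 3.33 CPM (log2 -1.41, SE 0.258) and Fmn2 to 4.50 ± 2.96 CPM (log2 -1.03, SE 0.185), both with an adjusted p of 0.0146. Their sign was shared by 4 of 4 strains, as the rule required. These contrasts share the American libraries with the Mediterranean ones. Cyp3a11 has close paralogs, so its value depends on how shared reads were divided. The counts against American were 21 genes, 8 higher and 13 lower. Cholesterol synthesis genes were higher as a group, 23 of 25, with a median log2 difference of 0.35 (camera adjusted p = 7.02e-10, adjusted p = 0.672 with an estimated correlation); 0 passed over all genes and 5 when adjusted over the list alone. Cyp51, a sterol demethylase, had 102 ± 18.1 against 165 ± 43.5 CPM (adjusted p = 0.0563), and Sqle, squalene epoxidase, 36.9 ± 11.1 against 76.2 ± 30.7 CPM (adjusted p = 0.086). Genes of amino acid breakdown and the urea cycle were lower in all but 2 of 27 (camera adjusted p = 1.39e-05, adjusted p = 0.672 with an estimated correlation), 0 past over all genes and 5 adjusted over the list alone. Cth, which makes cysteine, stood at 295 ± 52.3 against 224 ± 52.0 CPM (adjusted p = 0.0691). The vegan count ran from 4 without DBA/2J mouse 34 (American) to 169 without C57BL/6J mouse 16 (vegan), and 11 libraries moved it by over 1.5 times; DESeq2 called 116, limma on TPM 7 and the averaged 16-cell model 51.

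On the vegetarian diet no single liver gene passed. Genes of fatty acid oxidation and ketogenesis were lower as a group: 2 of 28 had higher means, with a median log2 difference of -0.17 (camera adjusted p = 4.16e-13, adjusted p = 0.437 with an estimated correlation), 0 past over all genes and 0 adjusted over the list alone. Cyp4a10, which oxidises fatty acids, stood at 210 ± 184 against 80.9 ± 63.8 CPM (SD, n = 8 each, adjusted p = 0.704). Bile acid genes were lower in all but 1 of 19 (median log2 difference -0.20, camera adjusted p = 3.77e-08, adjusted p = 0.125 with an estimated correlation), 0 past over all genes and 1 adjusted over the list alone. This was Abcb4, the phospholipid exporter of bile, at 261 ± 45.7 against 210 ± 43.4 CPM. Cholesterol synthesis genes were higher in 24 of 25 (median log2 difference 0.27, camera adjusted p = 2.99e-11, adjusted p = 0.672 with an estimated correlation), 0 past over all genes and 2 adjusted over the list alone, with Sqle at 36.9 ± 11.1 against 69.2 ± 33.8 CPM. The count against American was 0 with edgeR, beside 923 genes at an unadjusted p under 0.05, 4 with DESeq2 and 0 with limma on TPM. Leaving out SJL mouse 59 (vegetarian) gave 4 genes, and 4 libraries changed the count when left out. Over all 4 diets 19 liver genes were called, 223 with DESeq2, 2 with limma on TPM and 69 with the averaged 16-cell model, from 2 without mouse 34 to 77 without mouse 16, with 9 libraries moving it by over 1.5 times. Of the 108 list tests on liver diets, camera called 35 with the preset correlation, 0 with an estimated one, and fry 0.

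In brown fat lymphocyte genes were highest on the American diet. Ptpn6, a phosphatase of blood cells, fell from 9.29 ± 5.64 CPM on the American to 4.09 ± 1.21 on the Mediterranean and 4.09 ± 1.63 on the vegetarian diet (SD, n = 8 each; log2 -1.11 and -1.14, SE 0.214 and 0.215, adjusted p = 0.0356 and 0.0295). Cnn2, an actin binding calponin, fell on the vegetarian diet from 23.8 ± 7.52 to 15.9 ± 3.83 CPM (log2 -0.58, SE 0.112, adjusted p = 0.0295). Tmem63a, an ion channel gated by stretch, fell from 18.0 ± 4.24 to 14.0 ± 3.03 on the Mediterranean and 13.3 ± 2.86 CPM on the vegan diet (log2 -0.36 and -0.43, SE 0.0755 and 0.0756, adjusted p = 0.048 and 0.0318; 0.0728 and 0.075 without the count filter). In all of these the sign was shared by 4 of 4 strains, which the rule for naming genes required. In the T cell group 0 of 18 genes had higher means on the Mediterranean, vegetarian or vegan diet. Its median log2 differences were -1.64, -1.54 and -1.47 (camera adjusted p = 4.77e-12, 1.05e-11 and 2.69e-09; adjusted p = 0.576, 0.576 and 0.605 with an estimated correlation). Adjusted over the list alone 18, 17 and 17 members were lower, and 0 over all genes. In the B cell group, also with 0 of 15 higher, the medians were -1.85, -1.85 and -1.38 (camera adjusted p = 1.32e-12, 2.86e-12 and 1.12e-07; adjusted p = 0.576, 0.576 and 0.605 with an estimated correlation). Here 14, 14 and 15 were lower adjusted over the list alone. Blk, a kinase of the B cell receptor, was the 1 member past the test over all genes, on the vegetarian diet, at 1.47 ± 1.87 against 0.124 ± 0.104 CPM (log2 -3.43, SE 0.69, adjusted p = 0.0295).

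These lymphocyte genes were concentrated in 3 American libraries, those of C57BL/6J mouse 1, DBA/2J mouse 33 and SJL mouse 50, in which Cd79a, part of the B cell receptor, exceeded 4 times the tissue's median of 1.25 CPM, at 12.9, 18.8 and 6.45 CPM (unscaled). Next came SJL mouse 64, on the vegan diet, at 4.91 CPM, so the limit of 4 times, set after the values were seen, falls between close values. Without the 3 libraries the B cell medians on the Mediterranean, vegetarian and vegan diets were -0.66, -0.60 and -0.20 (camera adjusted p = 0.00134, 0.00652 and 0.385). The T cell medians were -0.52, -0.37 and -0.41 (camera adjusted p = 0.0096, 0.0344 and 0.127). Genes of heat production in brown fat were higher on the Mediterranean diet in 21 of 23, with a median log2 difference of 0.22 (camera adjusted p = 1.68e-09, adjusted p = 0.456 with an estimated correlation). On the vegan diet they were higher in 20 of 23 (median 0.25, camera adjusted p = 9.53e-06, adjusted p = 0.576 with an estimated correlation), and on the vegetarian diet in 18 of 23 (camera adjusted p = 0.000804, adjusted p = 0.605 with an estimated correlation). Over all genes 0 members passed, and 5, 4 and 1 did when adjusted over the list alone. Without the 3 libraries just named the medians on the Mediterranean, vegan and vegetarian diets were 0.17, 0.20 and 0.05 (camera adjusted p = 1.91e-05, 0.00216 and 0.0664), with 0 members past in either adjustment. Without the 5 libraries with liver transcripts, among them those of the American mice 17 and 49, they were 0.25, 0.21 and 0.14 (camera adjusted p = 1.69e-06, 0.000938 and 0.0706). Ucp1 stood at 5990 ± 2080 on the American and 8270 ± 1120 CPM on the Mediterranean diet (SD, n = 8 each, log2 0.54, SE 0.152, adjusted p = 0.113). Cpt1b, which brings fatty acids into mitochondria, stood at 521 ± 68.2 against 634 ± 40.6 CPM (adjusted p = 0.0669). Of 20210 genes, 84 were called over all diets, 21 against the Mediterranean diet (all lower than American), 54 against the vegetarian (all lower) and 3 against the vegan, 1 higher and 2 lower. DESeq2 called 280, 214, 205 and 254, and limma on TPM 0, 0, 0 and 2. With Cd79a as a covariate, or without the 3 libraries, edgeR called 0 genes in each of these 4 tests, with 2228, 2583, 2151 and 2213 genes at an unadjusted p under 0.05 with the covariate. With it the log2 change on the Mediterranean and vegetarian diets was -0.57 (SE 0.203) and -0.61 (SE 0.202) for Ptpn6. Cnn2 had -0.41 (SE 0.124) on the vegetarian diet, and Tmem63a -0.27 (SE 0.0877) and -0.36 (SE 0.0801) on the Mediterranean and vegan diets. Their adjusted p became 0.212, 0.356, 0.322, 0.183 and 0.123, as the changes shrank and the errors changed less. Without the 5 libraries with liver transcripts the counts were 336, 322, 379 and 441, of which 82, 21, 49 and 3 were among those called with all libraries. Left out singly, the library of C57BL/6J mouse 1 gave 1 and 0 genes over all diets and on the Mediterranean diet, that of SJL mouse 50 gave 0 on the vegetarian and that of C57BL/6J mouse 13 gave 0 on the vegan diet. The highest counts were 233 and 325 without A/J mouse 17 over all diets and on the vegetarian diet, 207 without A/J mouse 22 on the Mediterranean and 102 without SJL mouse 49 on the vegan diet. In these 4 tests 25, 18, 23 and 18 libraries each moved the count by over 1.5 times.

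**Figure D3:**
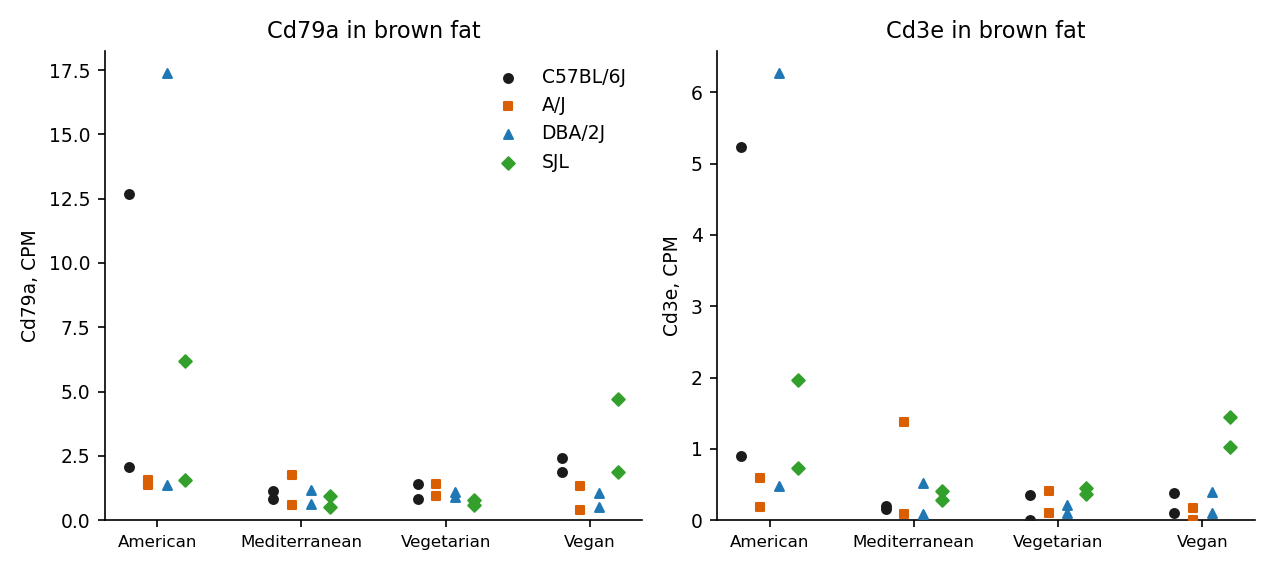
Brown fat levels by mouse, with diets along the horizontal axis, CPM on the vertical axis and points coloured by strain. The American libraries of mice 1, 33 and 50 stand above the other 5, which lie among the other diets.

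In muscle, subcutaneous fat and visceral fat edgeR called 0 genes over all diets and 0 for each diet against American. At an unadjusted p under 0.05 muscle had 590 genes over all diets and 982, 309 and 575 for the Mediterranean, vegetarian and vegan diets; DESeq2 called 4, 1, 0 and 0 and limma on TPM 0, 1, 0 and 0. In subcutaneous fat the unadjusted counts were 729, 913, 696 and 913, DESeq2 called 0, 0, 7 and 83, and limma on TPM 0. In visceral fat they were 999, 1161, 774 and 1840 (1 gene over all diets passed without the 12 libraries, and 1 with the marker covariates), with 0, 7, 2 and 31 by DESeq2 and 0 by limma on TPM; the averaged 16-cell model called 14 over all diets. Cholesterol synthesis genes in subcutaneous fat were lower on the vegan diet, all but 4 of 25 (median log2 difference -0.25, camera adjusted p = 9.67e-08, adjusted p = 0.977 with an estimated correlation), with 0 past over all genes and 6 adjusted over the list alone. Insig1, a brake on sterol synthesis, stood at 264 ± 98.2 against 146 ± 60.5 CPM (SD, n = 8 each, log2 -0.87, SE 0.192, adjusted p = 1). In visceral fat cell cycle genes were lower on the vegan diet in 16 of 16 (median log2 difference -0.70, camera adjusted p = 1.04e-16, adjusted p = 0.673 with an estimated correlation), 0 past over all genes and 14 adjusted over the list alone. The American libraries there include those of mice 49 and 50 and the vegan ones those of mice 13 and 16, with liver transcripts or the markers of the other depot. The median was -0.57 without mouse 50 and -0.75 without these 4. Without all 12 such libraries it was -0.84, with 15 of 16 lower adjusted over the list alone. Bub1, a mitotic checkpoint kinase, stood at 2.17 ± 1.07 against 0.940 ± 0.504 CPM (adjusted p = 0.418). Visceral genes of amino acid breakdown, which liver expresses strongly, were higher on the vegan diet in 27 of 27 (camera adjusted p = 1.72e-05, adjusted p = 0.673 with an estimated correlation), beside the Alb shares of 62.2% and 55.7% in mice 13 and 16. Without the 12 libraries their median log2 difference went from 1.38 to -0.46 (camera adjusted p = 0.221). Camera called 16 of 105 list tests in muscle, 37 of 105 in brown fat, 31 of 108 in subcutaneous and 55 of 114 in visceral fat, and 0 in each with an estimated correlation or with fry.

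Between the 4 strains, several genes with known variants differed in their carriers in the tissues named first. Nnt, a mitochondrial transhydrogenase that C57BL/6J mice lack in full length, was lower in C57BL/6J liver at 24.8 ± 4.06 (SD, n = 8) against 58.5 ± 10.1 CPM (n = 24; log2 -1.23, SE 0.0859, adjusted p = 4.39e-13). Dysf, the membrane repair gene disrupted in A/J, was lower in A/J muscle at 14.5 ± 2.04 against 89.8 ± 27.7 CPM (log2 -2.59, SE 0.136, adjusted p = 1.19e-14), while SJL, which carries a splice variant of it, was higher at 120 ± 4.83 CPM (log2 1.49, SE 0.107). Gpnmb, a glycoprotein with a stop codon in DBA/2J, was lower in DBA/2J muscle at 0.519 ± 0.351 against 19.5 ± 12.0 CPM (log2 -5.04, SE 0.35, adjusted p = 8e-12). Hc, complement component 5, deficient in A/J and DBA/2J, stood at 267 ± 62.3 and 256 ± 73.7 CPM in their livers against 1020 ± 211 in C57BL/6J and 1060 ± 190 in SJL. Glo1, duplicated in A/J and DBA/2J, was higher in their livers at 1180 ± 161 and 1040 ± 272 CPM against 477 ± 38.6 and 391 ± 71.6. Klrd1, the natural killer receptor CD94 that DBA/2J lacks, was lower in DBA/2J subcutaneous fat at 1.14 ± 0.159 against 11.9 ± 4.10 CPM (log2 -3.35, SE 0.29, adjusted p = 6.23e-10). Not every tissue showed these differences, and some values turned on the libraries with liver transcripts or the other depot's markers. Nnt in C57BL/6J visceral fat stood at 24.0 ± 16.7 against 23.3 ± 6.98 CPM (log2 -0.05, SE 0.188, adjusted p = 0.882), with a log2 of -0.67 (adjusted p = 0.000194) without the 12 visceral libraries named above. Gpnmb and Klrd1 did not pass in DBA/2J brown fat (adjusted p = 0.267 and 0.778, and 0.33 and 0.579 without the 5 brown libraries). Glo1 did not pass in visceral fat of A/J and DBA/2J (adjusted p = 0.667 and 0.329) or in A/J subcutaneous fat (adjusted p = 0.103). Without such libraries it was higher in A/J visceral (log2 1.06, adjusted p = 1.9e-05) and A/J subcutaneous fat (log2 1.20, adjusted p = 1.03e-08), while DBA/2J visceral fat had an adjusted p of 0.399. Outside liver Hc did not pass in A/J muscle, brown, subcutaneous and visceral fat (adjusted p = 0.388, 0.897, 0.427 and 0.725), nor in DBA/2J muscle, brown and visceral fat (adjusted p = 0.717, 0.967 and 0.234). Without such libraries it was higher in A/J muscle (log2 2.45, adjusted p = 0.0186). In DBA/2J subcutaneous fat it stood at 84.1 ± 135 against 9.23 ± 20.5 CPM (log2 3.35, SE 1.11, adjusted p = 0.0163). There mice 34, 38 and 45 hold Alb at 29.1%, 54.4% and 12.5% of the liver mean. Without the 5 such libraries log2 was -0.62 (adjusted p = 0.684).

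**Figure D4:**
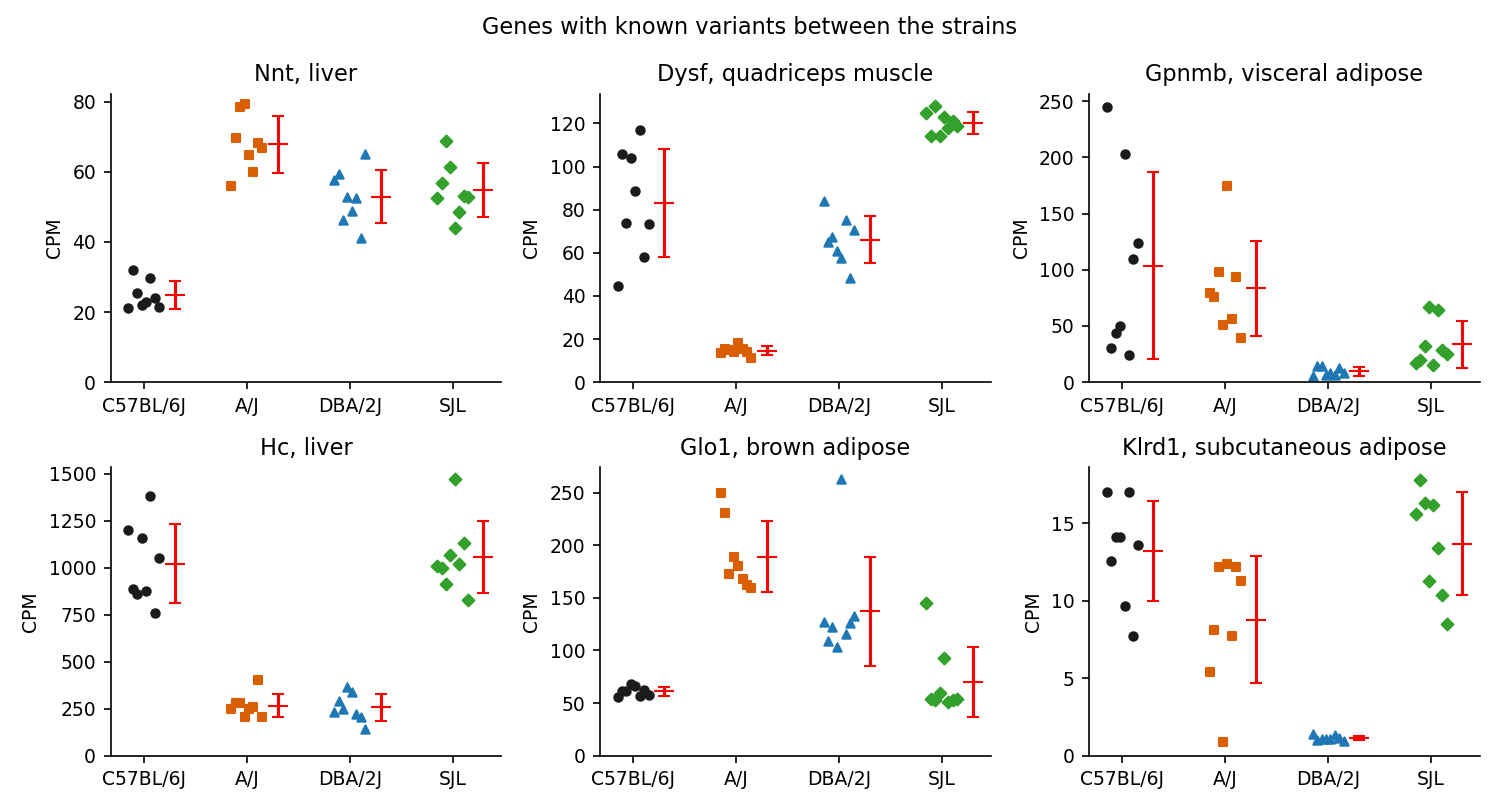
CPM (vertical axis) of 6 genes with known variants, by strain (horizontal axis), 1 point per mouse and bars at the mean ± SD of 8 mice, each in the tissue named above its panel. Dysf in A/J muscle stands at 14.5 ± 2.04 CPM and Klrd1 in DBA/2J subcutaneous fat at 1.14 ± 0.159 CPM.

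The test over strains called 9875 of 18636 genes in liver (53.0%), 9150 of 20118 in muscle (45.5%), 11479 of 20210 in brown fat (56.8%), 15418 of 23508 in subcutaneous fat (65.6%) and 9108 of 22715 in visceral fat (40.1%). DESeq2 called 10042, 10016, 11686, 15580 and 9716, and limma on TPM 6613, 9043, 9835, 11261 and 6107. No library changed a count by over 1.5 times when left out. Without the libraries named above the counts were 11031 in muscle, 10593 in brown, 14345 in subcutaneous and 7028 in visceral fat, with 8080, 9950, 13450 and 6034 genes shared with the full sets. Relaxed alignment for the strains other than C57BL/6J is confounded with strain, so differences between C57BL/6J and the rest include it.

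In liver the largest rise of each strain against the mean of the others was Moxd1, a monooxygenase, in C57BL/6J (53.5 ± 48.3 against 0.249 ± 0.398 CPM; SD, n = 8 and 24) and Slc28a1, a nucleoside transporter, in A/J (22.6 ± 14.5 against 0.241 ± 0.329). For the other strains it was Obp2a, an odorant binding protein, in DBA/2J (321 ± 186 against 4.17 ± 8.78) and the microRNA gene Mir692-2 in SJL (140 ± 33.4 against 0.895 ± 1.54). The largest falls were Cyp2b9 in C57BL/6J (0.461 ± 0.622 against 68.1 ± 105 CPM), Moxd1 in A/J (0.0345 ± 0.0678 against 18.1 ± 37.0), Zfp970 in DBA/2J (0.108 ± 0.0659 against 19.4 ± 9.87) and Cyp4a14 in SJL (7.99 ± 13.2 against 435 ± 554). Obp2a, Mir692-2, Zfp970 and the Cyp genes have near copies, so their levels are uncertain where reads were shared. Male-biased genes were lower in A/J liver in 12 of 12 (median log2 difference -0.60, camera adjusted p = 1.95e-06, adjusted p = 0.986 with an estimated correlation), 9 past over all genes and 9 adjusted over the list alone. Mup20, a urinary pheromone protein, stood at 58.6 ± 31.9 against 1480 ± 1560 CPM (log2 -3.97, SE 0.331) and Selenbp2 at 54.8 ± 30.6 against 986 ± 799 CPM. Interferon response genes were higher in DBA/2J liver in 23 of 28 (median 0.52, camera adjusted p = 6.89e-08, adjusted p = 0.986 with an estimated correlation), 18 past over all genes and 20 higher adjusted over the list alone.

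In muscle SJL differed from the others in 7488 genes, 4207 higher and 3281 lower, against 5496 in C57BL/6J, 2389 in A/J and 3144 in DBA/2J. Genes of muscle regeneration were higher in SJL in 11 of 14 (median log2 difference 1.32, camera adjusted p = 4.03e-05, adjusted p = 0.337 with an estimated correlation), 9 past over all genes and 9 adjusted over the list alone. Ankrd1, a stress-responsive titin partner, stood at 43.6 ± 13.8 (SD, n = 8) against 7.73 ± 3.11 CPM (n = 24; log2 2.57, SE 0.114, adjusted p = 1.47e-16). Mymk, which fuses myoblasts, was at 9.62 ± 2.43 against 1.02 ± 1.05 CPM (log2 3.87, SE 0.337) and Myog, a myogenic transcription factor, at 18.1 ± 4.53 against 6.52 ± 3.72 CPM (log2 1.64, SE 0.154). The interferon response was higher in 28 of 28 (median 1.43, camera adjusted p = 5.99e-14, adjusted p = 0.357 with an estimated correlation; 27 past over all genes and 27 adjusted over the list alone). Macrophage genes were higher in 19 of 20 (median 1.41, camera adjusted p = 5.99e-14, adjusted p = 0.135 with an estimated correlation; 18 past and higher, 19 adjusted over the list alone), such as Cd68 at 31.5 ± 6.77 against 8.80 ± 3.63 CPM. Cell cycle genes were higher in 15 of 16 (median 1.52, camera adjusted p = 1.73e-08, adjusted p = 0.0931 with an estimated correlation; 15 past and higher and 1 past and lower in both adjustments). Top2a, a topoisomerase of dividing cells, stood at 4.75 ± 0.824 against 1.13 ± 0.508 CPM. Ucp1 stood at 0.963 to 2.73% of the brown fat level in all 8 SJL muscle libraries, while it exceeded 0.5% in 0 of 8 C57BL/6J, 2 of 8 A/J and 1 of 8 DBA/2J libraries, with a maximum of 7.65%. With Alb and Ucp1 as covariates SJL differed in 4295 genes, and without the 9 libraries with liver transcripts, none from SJL, in 7771. For C57BL/6J, A/J and DBA/2J the counts were 3082, 2828 and 3285 with the covariates, and 7052, 4175 and 2583 without the 9 libraries. SJL kept the highest count in both, while the order of the other 3 changed. With the covariates 7 of 14 regeneration genes, 28 of 28 of the interferon response and 18 of 20 macrophage genes were past and higher. Because Ucp1 in muscle goes with the strain, the covariate also takes up differences between strains, and the cause of its level was not tested. In DBA/2J muscle the macrophage group was lower in all but 1 of 20 (median -0.83, camera adjusted p = 2.56e-09, adjusted p = 0.233 with an estimated correlation; 14 past over all genes and 15 adjusted over the list alone). Each strain was set against the mean of the other 3, so these contrasts share libraries. The largest rises were mt-Tg in C57BL/6J, Rps3a3 in A/J, Tmem232 in DBA/2J and Mir692-2 in SJL, and the largest falls Ifi202b, Tmem232, Gpnmb and Mup13 in the same order; all but Tmem232 and Gpnmb have near copies. Mup13, a liver pheromone gene, stood at 0.241 ± 0.230 in SJL against 51.7 ± 180 CPM, and its adjusted p of 0.0065 became 0.234 without the 9 libraries with liver transcripts. The share of the called C57BL/6J genes that was higher was 47.9% with TMM and 52.6% with RLE scaling.

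In brown fat Rufy4, an autophagy gene, stood out in DBA/2J at 598 ± 179 (SD, n = 8) against 4.24 ± 1.5 CPM (n = 24; log2 7.18, SE 0.142, adjusted p = 4.79e-25). The other largest rises were Cyp1a1, a cytochrome induced by dioxin-like compounds, in C57BL/6J (20.7 ± 21.2 against 0.656 ± 0.925 CPM), Slc28a1 in A/J (48.0 ± 27.5 against 1.09 ± 2.82) and Acp3, an acid phosphatase, in SJL (22.8 ± 6.77 against 0.256 ± 0.485). The largest falls were Myh6, the cardiac myosin heavy chain, in C57BL/6J (0.322 ± 0.173 against 20.1 ± 18.8), Ptgds, a prostaglandin synthase, in A/J and DBA/2J (0.110 ± 0.112 and 0.1 ± 0.118 against 9.57 ± 8.19 and 9.57 ± 8.18), and Zfp982 in SJL (0.206 ± 0.179 against 9.96 ± 6.55). Interferon response genes were lower in A/J in 28 of 28 (median log2 difference -1.07, camera adjusted p = 4.08e-14, adjusted p = 0.936 with an estimated correlation), 23 past over all genes and 25 adjusted over the list alone, with Ifit3 at 1.5 ± 0.591 against 6.54 ± 2.27 CPM. In SJL they were higher in 28 of 28 (median 0.93, camera adjusted p = 2.52e-14, adjusted p = 0.936 with an estimated correlation), 24 past over all genes and 25 adjusted over the list alone. Cell cycle genes were higher in DBA/2J in 16 of 16 (median 1.52, camera adjusted p = 9.97e-11, adjusted p = 0.936 with an estimated correlation), all 16 past in both adjustments. Genes of fat expansion were higher in DBA/2J in 6 of 6 (median 1.19, camera adjusted p = 0.0043, adjusted p = 0.998 with an estimated correlation), all 6 past in both adjustments. Lep, the satiety hormone, stood at 351 ± 61.4 against 105 ± 99.2 CPM (log2 2.06, SE 0.349).

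In subcutaneous fat SJL had high levels of heat production genes: 20 of 23 were higher (median log2 difference 2.25, camera adjusted p = 2.8e-08, adjusted p = 0.855 with an estimated correlation), 19 past over all genes and 19 adjusted over the list alone. Cox8b, a subunit of cytochrome oxidase typical of brown fat, stood at 266 ± 83.1 (SD, n = 8) against 53.6 ± 37.9 CPM (n = 24; log2 2.43, SE 0.25, adjusted p = 1.66e-08). Oxidative phosphorylation genes were higher in 22 of 22 (median 0.80, camera adjusted p = 3.55e-13, adjusted p = 0.855 with an estimated correlation; 22 past in both adjustments). Genes of the extracellular matrix were lower in SJL in all but 1 of 26 (median -1.14, camera adjusted p = 3.5e-14, adjusted p = 0.855 with an estimated correlation), 25 past in both adjustments. Col6a1, a collagen chain, stood at 237 ± 35.5 against 644 ± 141 CPM (log2 -1.43, SE 0.127). The fat expansion group was lower in 6 of 6 (camera adjusted p = 6.88e-05, adjusted p = 0.855 with an estimated correlation; 6 past in both adjustments), with Mest, an imprinted hydrolase, at 24.4 ± 8.03 against 251 ± 192 CPM. Ucp1 stood at 14.8 to 45.1% of the brown fat mean in all 8 SJL subcutaneous libraries, and exceeded 10% in 1 of 8 C57BL/6J, 1 of 8 A/J and 0 of 8 DBA/2J libraries. With Alb, Ckm and Ucp1 as covariates the genes called in SJL fell from 10301 to 3780. Of the heat production genes 3 were then past and higher and 2 past and lower (median 0.59), 6 oxidative phosphorylation genes were past and higher, and 18 matrix and 6 fat expansion genes past and lower. Ucp1 is itself a heat production gene and goes with the strain, so this covariate removes part of what is compared. Whether brown fat was taken along or the depot itself differs was not tested. In DBA/2J cholesterol synthesis genes were higher in 24 of 25 (camera adjusted p = 7.59e-08, adjusted p = 0.855 with an estimated correlation), 23 past over all genes and 23 adjusted over the list alone. Liver expresses this pathway strongly, and mice 34, 38 and 45 of this strain carry the Alb shares given above; without the 5 libraries the median went from 0.78 to 0.59, with 18 past over all genes. The largest rises were Trim12a in C57BL/6J, Slc28a1 in A/J, Mcpt2 in DBA/2J and Zfp990 in SJL, and the largest falls Ifi202b, Apol7c, Ffar1 and H2-Ea in the same order. Ffar1, a receptor for fatty acids, stood at 0.185 ± 0.102 against 10.7 ± 5.26 CPM. H2-Ea, an MHC class II chain with known null alleles, stood at 1.55 ± 2.62 against 208 ± 184 CPM.

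In visceral fat the extracellular matrix group was higher in DBA/2J in 25 of 26 (camera adjusted p = 2.01e-12, adjusted p = 0.934 with an estimated correlation), 20 past over all genes and 21 adjusted over the list alone. It was lower in SJL in all but 1 of 26 (camera adjusted p = 1.13e-10, adjusted p = 0.934 with an estimated correlation), 18 past over all genes and 18 lower adjusted over the list alone. Fbn1, the microfibril protein fibrillin, stood at 691 ± 137 against 285 ± 130 CPM in the first contrast (SD, n = 8 and 24; log2 1.37, SE 0.16) and at 178 ± 56.7 against 456 ± 211 CPM in the second (log2 -1.25, SE 0.185). Interferon response genes were higher in SJL in 27 of 28 (camera adjusted p = 2.01e-12, adjusted p = 0.934 with an estimated correlation), 18 past over all genes and 20 adjusted over the list alone. Of the 8 SJL visceral libraries those of mice 49 and 57 hold Alb at 38.9% and 41.1% of the liver mean, that of mouse 64 holds 11.7% of the C57BL/6J liver genes, and that of mouse 50 resembles subcutaneous fat. Without the 12 libraries named above the genes called in SJL fell from 3994 to 2327. The SJL matrix median went from -0.68 to -0.51 (13 past and lower, 1 past and higher) and the interferon median from 0.54 to 0.58 (16 past). In DBA/2J the matrix median went from 0.81 to 0.67, with 20 past. The largest rises were Ceacam10 in C57BL/6J, Rps3a3 in A/J, Brinp2 in DBA/2J and Mir692-2 in SJL, and the largest falls Slc28a2b, Ceacam10, Zfp970 and H2-Ea in the same order. Brinp2, a neural cell cycle regulator, stood at 40.2 ± 7.31 against 0.520 ± 1.08 CPM. Ceacam10, a secreted adhesion protein, rested on C57BL/6J mouse 8 alone, at 772 CPM, and its contrast in A/J had an adjusted p of 0.2. Over the 5 tissues camera called 27 of 144, 53 of 140, 23 of 140, 41 of 144 and 34 of 152 strain list tests in liver, muscle, brown, subcutaneous and visceral fat. With an estimated correlation it called 0, and fry called 43, 54, 27, 39 and 18, of which 26, 41, 18, 30 and 14 were camera calls.

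The interaction asked whether the strains respond differently to the diets. In visceral fat 89 genes passed, and the 4 with the smallest p were H2-T7, H2-T5, Dpy19l3 and C1rb (adjusted p = 0.00207 each). C1rb, a complement protease, stood at 32.5 and 31.6 CPM in C57BL/6J vegan mice 13 and 16 against 0.782 to 4.11 CPM in the other 6 C57BL/6J mice. Dpy19l3, a mannosyltransferase, stood at 33.0 and 32.8 against 7.84 to 12.3 CPM. The class Ib MHC genes H2-T5 and H2-T7, which have near copies, stood at 19.8 and 15.2, and 5.93 and 5.4 CPM. These are the libraries with 55.4% and 52.7% of the DBA/2J liver genes. Within C57BL/6J 1210 visceral genes differed between diets, 167 without mouse 13, and 5 of the 8 libraries moved that count by over 1.5 times. The visceral interaction count ran from 24 without mouse 13 to 1078 without SJL mouse 59, with 24 libraries moving it by over 1.5 times; DESeq2 called 1932 and limma on TPM 11. The 12 libraries named above include both vegan C57BL/6J and both American SJL libraries. Over the 14 cells left without them edgeR called 0 interaction genes, beside 584 at an unadjusted p under 0.05, and 5 genes between the 3 diets left within C57BL/6J. No other tool was run on these cells. In brown fat 2 genes passed, among them H2-T15 (adjusted p = 0.0293, 0.0861 without the count filter and 0.084 with Cd79a as a covariate), at 3.83 and 2.7 CPM in C57BL/6J American mice 1 and 2 against 0 to 0.187 CPM in the other C57BL/6J mice. DESeq2 called 514 there and limma on TPM 1, and 85 passed without the 5 libraries with liver transcripts. The count ran from 1 without C57BL/6J mouse 1 to 7 without C57BL/6J mouse 16, and 26 libraries moved it by over 1.5 times.

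Liver, muscle and subcutaneous fat had 0 interaction genes with edgeR, beside 1508, 1372 and 1243 at an unadjusted p under 0.05, 225, 54 and 138 with DESeq2 and 0 with limma on TPM. Left out singly, SJL mouse 54 in liver, SJL mouse 63 in muscle and A/J mouse 22 in subcutaneous fat gave 41, 269 and 363 genes. Over the 15 muscle cells left without the 9 libraries with liver transcripts 2 genes passed, and 16 in subcutaneous fat without its 5 libraries. With 2 mice per cell this test had little reach: in simulated data 5.97% of the added 2-fold interactions in liver were recovered and 0% in visceral fat, against 74.6% of the 2-fold changes between the vegan and American diets in liver. Within the strains edgeR called in liver 0 genes in C57BL/6J (2166 at an unadjusted p under 0.05), 13 in A/J, 10 in DBA/2J and 1 in SJL, and in muscle 2, 4, 1 and 0 (567 unadjusted in SJL). In brown fat the counts were 55, 6, 0 (1109 unadjusted in DBA/2J) and 1, in subcutaneous fat 0, 6, 0 and 0 (932, 1570 and 1174 unadjusted in C57BL/6J, DBA/2J and SJL) and in visceral fat outside C57BL/6J 13, 5 and 0 (2308 unadjusted in SJL). No other tool was run within strains. Without the libraries named in the opening paragraphs, edgeR called 13 and 40 muscle genes in C57BL/6J and A/J, and 0 in DBA/2J and SJL (874 and 658 unadjusted, DBA/2J over the diets left). Brown fat then had 40, 1437, 1 and 10, and subcutaneous fat 0, 0, 34 and 9 (1292 and 1938 unadjusted in C57BL/6J and A/J). Visceral fat had 1 in A/J, and 0 in DBA/2J and SJL (381 and 311 unadjusted, SJL over the diets left). With 1 library left out the highest counts in liver were 85 (mouse 9), 14 (mouse 17), 356 (mouse 48) and 923 (mouse 54), with strains in the same order. In muscle they were 300 (mouse 8), 7 (mouse 30), 27 (mouse 33) and 595 (mouse 63), and in brown fat 160 (mouse 2), 1131 (mouse 17), 188 (mouse 34) and 62 (mouse 50). Subcutaneous fat had 21 (mouse 13), 1433 (mouse 22), 385 (mouse 39) and 31 (mouse 63), and visceral fat outside C57BL/6J 436 (mouse 22), 17 (mouse 40) and 1929 (mouse 49). These counts do not show that strains differ in their response, which only the interaction tests.

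The last comparison set visceral against subcutaneous fat. Visceral fat was higher in genes of the mesothelium, the cell layer that lines the body cavity: all 7 of the group were higher and past the test over all genes (median log2 difference 6.17, camera adjusted p = 1.59e-10, adjusted p = 0.186 with an estimated correlation and 0.034 without mouse 50). Upk3b stood at 125 ± 46.1 against 1.12 ± 2.30 CPM (SD, n = 32 each; log2 7.66, SE 0.534, adjusted p = 3.01e-18). Msln, mesothelin, stood at 74.1 ± 27.0 against 1.18 ± 1.82 CPM (log2 6.40, SE 0.353). Muc16, a membrane mucin, was at 18.1 ± 9.34 against 0.172 ± 0.305 CPM (log2 7.10, SE 0.401) and Wt1 at 15.0 ± 4.71 against 0.195 ± 0.332 CPM (log2 6.61, SE 0.393). Upk1b and Bnc1, of the same group, were also among the 10 largest rises. The other 4, Cfap65, Dcdc2a, Cuzd1 and Foxj1, are outside that group and were uneven, with visceral medians of 2.87, 8.18, 5.46 and 4.58 CPM, maxima of 52.5, 96.0, 44.9 and 54.1 CPM, and under 1 CPM in 12, 8, 10 and 10 of 32 libraries. Over the visceral libraries they rose and fell together (correlations of 0.928 to 0.985), and less so with Wt1, Msln and Upk3b (0.0569 to 0.174) or with the epididymis and testis list (0.156 to 0.637). All 6 genes of that list were higher in visceral fat and past the test over all genes (median edgeR log2 4.58, camera adjusted p = 0.27, fry adjusted p = 0.0454). The visceral library of DBA/2J mouse 39, on the Mediterranean diet, held most of this, with 218 CPM of the epididymal gene Lcn8 against at most 4.34 CPM in any other, and without it 4 of 6 were past (median 1.51). Epididymis in that sample, and another tissue beside the fat as the source of the 4 uneven genes, were not excluded. Subcutaneous fat was higher in the groups for T cells, 18 of 18 (median -4.33, camera adjusted p = 2.12e-15, adjusted p = 0.356 with an estimated correlation), and B cells, 15 of 15 (median -3.93, camera adjusted p = 1.49e-10, adjusted p = 0.4 with an estimated correlation), all past the test over all genes. Of 38 lists between the depots camera called 23, 0 with an estimated correlation, and fry 27. Cd8a, a T cell co-receptor, stood at 4.46 ± 18.8 in visceral against 60.9 ± 37.6 CPM in subcutaneous fat (log2 -5.31, SE 0.488, adjusted p = 3.59e-14). Cr2, a complement receptor of B cells, was at 7.59 ± 28.4 against 96.6 ± 58.6 CPM (log2 -4.92, SE 0.436) and Glycam1, a ligand made by lymph node venules, at 2.54 ± 10.4 against 50.6 ± 39.1 CPM (log2 -6.05, SE 0.717). Dsc3, a desmosome gene of stratified epithelium, was at 1.16 ± 5.65 against 20.2 ± 9.76 CPM (log2 -6.23, SE 0.66). Nsg2, Cd8b1, Fcer2a, Treml2, H2-Eb2 and Sidt1 were the other large falls. The visceral library of mouse 50 lifts these visceral means, with 107, 162, 57.7 and 32.0 CPM of Cd8a, Cr2, Glycam1 and Dsc3. In the other 31 the means were 1.15 ± 1.78, 2.60 ± 3.50, 0.766 ± 2.64 and 0.161 ± 0.484 CPM. Without it the log2 differences were -5.70, -5.26, -6.58 and -7.10 (SE 0.398, 0.357, 0.661 and 0.522), and 16623 genes differed, 16320 of them also with it. Lymph node tissue taken with the subcutaneous fat was not excluded as the source of the T and B cell genes. Unscaled, Cd79a stood at 125 ± 62.3 CPM in subcutaneous (range 0.529 to 226), 10.7 ± 25.3 in visceral and 2.36 ± 3.81 CPM in brown fat. Scaled over both depots it was 133 CPM in the visceral library of mouse 50 and 6.49 ± 4.95 CPM in the other 31. Of 24468 genes 16380 (66.9%) differed, 8356 higher and 8024 lower in visceral fat, and DESeq2 called 16456 and limma on TPM 12219. For the 29 mice with both depots, paired by using the mouse as a block, the number of Visceral vs Subcutaneous Adipose genes was 16390, with 15546 of them also called without it. Residuals of the depots of 1 mouse were not alike (mean correlation -0.0727, against 0.00446 between mice).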

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

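For the visceral libraries of the vegan C57BL/6J mice the tests of a diet response and of a wrong label, for brown fat the test of lymph node tissue, and for mouse 50 the tests of subcutaneous fat and of an exchange were chosen only after the result was seen.

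In visceral fat the 4 interaction genes with the smallest p were H2-T7, H2-T5, Dpy19l3 and C1rb (adjusted p = 0.00207 each). The C57BL/6J vegan mice 13 and 16 stood apart from the other 6 C57BL/6J mice in all 4, and 1210 genes differed between diets within this strain. A mixture of C57BL/6J visceral RNA with 59% of DBA/2J liver RNA gave the observed vegan change within 1.5-fold for 92.4% of these genes, against 69.1% for a mixture with liver of the own strain and 22.9% for no change. Against a vegan response as the whole cause stands that DBA/2J liver genes that C57BL/6J lacks reached at least 52.7% of their level in both libraries. Alb at 55.7% of the liver level or more stands against a wrong label without liver RNA, but marks liver, not strain. Liver RNA of another strain is a candidate explanation. A wrong label with liver RNA, or a smaller diet response beside it, was not tested.

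In brown fat H2-T15 differed by the interaction term (adjusted p = 0.0293, 0.084 with Cd79a as a covariate and 0.0861 without the count filter), at the levels given above. The lymphocyte genes higher on the American diet sat in the libraries of mice 1, 33 and 50, where the T cell list had a median log2 difference of 3.19 to the other 5 American libraries. The macrophage list had 0.345 there, which argues against a general rise of immune cells; the B cell list is not used for this, since the libraries were chosen by the B cell gene Cd79a. In A/J, which holds none of the 3, the American minus other difference was 0.0816 for the B cell list and -0.0167 for the T cell list, against a rise on this diet in every strain, and 3 of the 3 libraries had totals within those of the other American libraries, against depth. Lymph node tissue taken with the fat may account for the pattern in these 3 libraries, while lymphocytes that entered the fat of these 3 mice stay open and were not tested.

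The visceral library of SJL mouse 50 was far from the other 7 of its strain in Wt1 at 0 CPM (median of the others 17.2), Klrd1 at 10.8 (1.64) and Nnt at 12.3 (26.4). Of 2469 genes that differ 4-fold or more between the depots, 87.3% lay nearer the subcutaneous mean, against a median of 17.1% and a maximum of 38.6% in the other 31 visceral libraries and 45.0% to 94.5% in subcutaneous ones. In this mouse's subcutaneous library 12.3% lay nearer the visceral mean (others up to 55.0%), against an exchange of the 2. In mouse 49, on the same diet, 15.7% lay nearer the subcutaneous mean, against a loss of visceral identity on this diet in SJL. The 2 libraries of mouse 50 were alike (chi-squared per degree of freedom 12.9, median of group pairs 62). Its subcutaneous fat in both is a candidate explanation. Whether by dissection or labelling was not tested.

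Among 206 groups of 8 libraries, 38 had 1 library far from the other 7. Chance gives 5% for normally distributed values, but some groups lie near 0 CPM, so no excess is shown. Besides the library of mouse 50 the 38 were these, in CPM with the median of the other 7 in brackets. Liver had Slc28a1 in A/J mouse 27 at 0 (23.9), Moxd1 in A/J mouse 18 at 0.196 (0), Cyp4a14 in SJL mouse 63 at 40.4 (2.71), Gpnmb in SJL mouse 59 at 0.405 (0.127) and Hc in A/J mouse 30 at 404 (251). It also had Klrd1 in DBA/2J mouse 42 at 0.0751 (0) and in SJL mouse 53 at 0 (0.301), and Alb in C57BL/6J mouse 7 at 101000 (54500). Muscle had Ifi202b in C57BL/6J mouse 8 at 3.76 (0.294), Mir692-2 in SJL mouse 64 at 46.6 (24.2), and Glo1 in A/J mouse 32 at 435 (321), DBA/2J mouse 45 at 643 (233) and SJL mouse 64 at 127 (79.5). Brown fat had Slc28a1 in A/J mouse 27 at 0.103 (51.9), Zfp982 in SJL mouse 49 at 0.603 (0.162), Gpnmb in DBA/2J mouse 48 at 0.594 (6.96) and Hc in C57BL/6J mouse 16 at 38.5 (0.308). There were also Glo1 in DBA/2J mouse 42 at 263 (122), Klrd1 in DBA/2J mouse 33 at 1.46 (0) and Ucp1 in SJL mouse 49 at 5060 (7700).

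Subcutaneous fat had Slc28a1 in A/J mouse 27 at 0.196 (72.6), H2-Ea in SJL mouse 64 at 7.91 (0.536), Nnt in SJL mouse 64 at 38.2 (14.2) and Gpnmb in SJL mouse 57 at 43.9 (12.5). Hc and Glo1 in C57BL/6J mouse 1 were at 12.9 (2.37) and 90.7 (49.1), Glo1 in DBA/2J mouse 38 at 811 (139) and in SJL mouse 64 at 407 (54.8). Klrd1 in A/J mouse 24 was at 0.88 (11.3) and Lep in DBA/2J mouse 38 at 1160 (2300). Visceral fat had Ceacam10 in C57BL/6J mouse 8 at 772 (0), H2-Ea in SJL mouse 53 at 8.65 (0.562), Nnt in A/J mouse 25 at 21.6 (29.6), Glo1 in DBA/2J mouse 45 at 303 (123) and Klrd1 in DBA/2J mouse 34 at 1.41 (0.218).

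The labels were reassigned 100 times, the real labels included. In liver only the real labels reached 19 genes over all diets (highest other 7). The same held for the 27 on the Mediterranean (5) and 21 on the vegan diet (4). Each is 1 of 100, under 5% per test, without correction for the number of tests. For the vegetarian diet 100 of 100 reached the real 0 (highest other 3), as any assignment must, so the comparison says nothing about chance there. In brown fat 10, 5, 5 and 7 of the 100 reached the real 84 over all diets and 21, 54 and 3 on the Mediterranean, vegetarian and vegan diets, so chance is not excluded. The highest others there were 908, 679, 916 and 525. Muscle, subcutaneous and visceral fat had a real count of 0 in each of these 4 tests, which 100 of 100 reached for the same reason. Their highest others were 1376, 2, 4 and 4592 in muscle, 1254, 1108, 822 and 1452 in subcutaneous and 554, 11, 19 and 402 in visceral fat. Assignments that call several times the real count point to a structure of the samples, and what it follows was not tested. For the strains 1 of 100 reached the real count in each tissue, so chance is excluded: 9875 in liver (highest other 201), 9150 in muscle (2446), 11479 in brown (608), 15418 in subcutaneous (1213) and 9108 in visceral fat (1582). For the depots 1 of 60 reached 16380 (highest other 3384).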

How the results depend on the processing

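The tests with other-tissue markers as covariates, with Cd79a, without the libraries above 4 times its median, and without the libraries holding liver transcripts or the other depot's markers, also over the cells left, were chosen only after the results were seen. A count is called moved when it differs from the reported one by over 1.5 times. The strain counts of all 5 tissues and the depot count stayed within that limit under each alternative run on them. Where counts moved, the cause was not tested unless stated.

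Size factors by RLE moved 2 of 51 counts and removing the filter 14 of 51. With RLE size factors the count became, in muscle, 1 (from 0) for the interaction. Brown fat gave 27 (from 54) for the vegetarian diet. Without the count filter the counts became, in liver, 6 (from 27) for the Mediterranean diet, 13 (from 0) within C57BL/6J and 3 (from 1) within SJL. Muscle gave 2 (from 0) for the interaction, 11 (from 2) within C57BL/6J and 2 (from 1) within DBA/2J. Brown fat gave 34 (from 54) for the vegetarian diet, 0 (from 3) for the vegan diet, 1 (from 2) for the interaction and 2 (from 0) within DBA/2J. Subcutaneous fat gave 1 (from 0) within C57BL/6J and 2 (from 0) within SJL. Visceral fat gave 11 (from 5) within DBA/2J and 103 (from 0) within SJL. Of 1596 values of named genes 1592 stayed on their side of the threshold with RLE, 1 was weaker and 3 stronger. Without the filter 1569 stayed, 26 were weaker and 1 reversed: Hc in DBA/2J brown fat, with a log2 difference of 0.000485 and an adjusted p of 1. With DESeq2 1509 of 1595 stayed, 1 was weaker and 85 stronger.

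The averaged 16-cell model moved 9 of 25 counts, limma on TPM 9 of 31 and DESeq2 20 of 31. The 16-cell model averaged over strains gave, in liver, 69 (from 19) for all diets, 95 (from 27) for the Mediterranean diet and 51 (from 21) for the vegan diet. Muscle gave 1 (from 0) for all diets. Brown fat gave 1 (from 84) for all diets, 1 (from 21) for the Mediterranean diet, 1 (from 54) for the vegetarian diet and 6 (from 3) for the vegan diet. Visceral fat gave 14 (from 0) for all diets. With limma on TPM the counts became, in liver, 2 (from 19) for all diets, 0 (from 27) for the Mediterranean diet and 7 (from 21) for the vegan diet. Muscle gave 1 (from 0) for the Mediterranean diet. Brown fat gave 0 (from 84) for all diets, 0 (from 21) for the Mediterranean diet, 0 (from 54) for the vegetarian diet and 1 (from 2) for the interaction. Visceral fat gave 11 (from 89) for the interaction. With DESeq2 the counts became, in liver, 199 (from 27) for the Mediterranean diet, 4 (from 0) for the vegetarian diet, 116 (from 21) for the vegan diet and 223 (from 19) for all diets. Further counts were 225 (from 0) for the interaction. Muscle gave 1 (from 0) for the Mediterranean diet, 4 (from 0) for all diets and 54 (from 0) for the interaction. Brown fat gave 214 (from 21) for the Mediterranean diet, 205 (from 54) for the vegetarian diet, 254 (from 3) for the vegan diet and 280 (from 84) for all diets. Next came 514 (from 2) for the interaction. Subcutaneous fat gave 7 (from 0) for the vegetarian diet, 83 (from 0) for the vegan diet and 138 (from 0) for the interaction. Visceral fat gave 7 (from 0) for the Mediterranean diet, 2 (from 0) for the vegetarian diet, 31 (from 0) for the vegan diet and 1932 (from 89) for the interaction.

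Within strains, 12 of 20 counts moved. Fitted on each strain's 8 libraries alone, which leaves fewer libraries to estimate the spread, the counts became, in liver, 0 (from 13) within A/J and 0 (from 1) within SJL. Muscle gave 0 (from 2) within C57BL/6J, 0 (from 4) within A/J and 0 (from 1) within DBA/2J. Brown fat gave 0 (from 55) within C57BL/6J, 1 (from 6) within A/J and 0 (from 1) within SJL. Subcutaneous fat gave 0 (from 6) within A/J. Visceral fat gave 2266 (from 1210) within C57BL/6J, 0 (from 13) within A/J and 0 (from 5) within DBA/2J.

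The covariates moved 11 of 43 counts, and leaving out libraries 17 of 38 and 4 of 5 over the cells left. Leaving out libraries left several cells with a lone library, assumed to vary like the rest. With Alb, Ckm and Ucp1 as covariates the counts became, in brown fat, 245 (from 21) for the Mediterranean diet, 16 (from 54) for the vegetarian diet, 21 (from 2) for the interaction and 19 (from 55) within C57BL/6J. Other ranges were 8 (from 0) within DBA/2J and 14 (from 1) within SJL. Subcutaneous fat gave 3 (from 0) within DBA/2J. Visceral fat gave 1 (from 0) for all diets, 559 (from 1210) within C57BL/6J, 1 (from 13) within A/J and 1 (from 0) within SJL. Without the libraries holding liver transcripts or the markers of the other depot the counts became, in muscle, 13 (from 2) within C57BL/6J and 40 (from 4) within A/J. Brown fat gave 336 (from 84) for all diets, 322 (from 21) for the Mediterranean diet, 379 (from 54) for the vegetarian diet and 441 (from 3) for the vegan diet. Next came 85 (from 2) for the interaction, 1437 (from 6) within A/J, 1 (from 0) within DBA/2J and 10 (from 1) within SJL. Subcutaneous fat gave 16 (from 0) for the interaction, 0 (from 6) within A/J, 34 (from 0) within DBA/2J and 9 (from 0) within SJL. Visceral fat gave 1 (from 0) for all diets, 1 (from 13) within A/J and 0 (from 5) within DBA/2J. Where both libraries of a cell were among them, the tests over the cells left gave, in muscle, 2 (from 0) for the interaction and 0 (from 1) within DBA/2J. Visceral fat gave 0 (from 89) for the interaction and 5 (from 1210) within C57BL/6J. Within SJL visceral fat it stayed at 0. In these tests 874 genes within DBA/2J in muscle, and 584 for the interaction and 311 within SJL in visceral fat, had an unadjusted p under 0.05, and no other tool was run.

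In brown fat both settings on Cd79a moved 7 of 12 counts. With Cd79a as a covariate the counts became, in brown fat, 0 (from 84) for all diets, 0 (from 21) for the Mediterranean diet, 0 (from 54) for the vegetarian diet and 0 (from 3) for the vegan diet. Then followed 1 (from 2) for the interaction, 23 (from 55) within C57BL/6J and 0 (from 1) within SJL. Without the 3 libraries with over 4 times the median of Cd79a the same 4 diet counts became 0 in brown fat. There were also 6 (from 2) for the interaction, 24 (from 55) within C57BL/6J and 30 (from 1) within SJL.

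The lists depended on the correlation between genes. With an estimated correlation the number of called list tests became 0 for diet and 0 for strain, and fry called 0 for diet. With the markers as covariates the number was 155 for diet and 174 for strain, and without the libraries holding liver transcripts or the other depot's markers 167 and 155. With Cd79a as a covariate in brown fat it was 172 and 179, and without its 3 libraries 170 and 178. Paired analysis of the depots, with the mouse as a replicate block, gave 16390 Visceral vs Subcutaneous Adipose genes. The same mouse numbers across tissues are the same animals, and the tissues were otherwise analysed apart.

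With each library left out in turn, which leaves 1 cell with a lone library assumed to vary like the rest, the counts ranged as follows, with the mouse left out. Liver had 2 (mouse 34) to 77 (mouse 16) for all diets, 0 (mouse 18) to 142 (mouse 39) for the Mediterranean diet and 0 (mouse 1) to 4 (mouse 59) for the vegetarian diet. Other ranges were 4 (mouse 34) to 169 (mouse 16) for the vegan diet, 9331 (mouse 54) to 10422 (mouse 53) for all strains and 0 (mouse 1) to 41 (mouse 54) for the interaction. Then followed 0 (mouse 1) to 85 (mouse 9) within C57BL/6J, 1 (mouse 18) to 14 (mouse 17) within A/J and 0 (mouse 34) to 356 (mouse 48) within DBA/2J. There were also 0 (mouse 49) to 923 (mouse 54) within SJL. Muscle had 0 (mouse 1) to 1 (mouse 8) for all diets, 8246 (mouse 63) to 9912 (mouse 8) for all strains and 0 (mouse 12) to 269 (mouse 63) for the interaction. Further counts were 0 (mouse 13) to 300 (mouse 8) within C57BL/6J, 2 (mouse 27) to 7 (mouse 30) within A/J and 0 (mouse 38) to 27 (mouse 33) within DBA/2J. Next came 0 (mouse 49) to 595 (mouse 63) within SJL. Brown fat had 1 (mouse 1) to 233 (mouse 17) for all diets, 0 (mouse 1) to 207 (mouse 22) for the Mediterranean diet and 0 (mouse 50) to 325 (mouse 17) for the vegetarian diet. Other ranges were 0 (mouse 13) to 102 (mouse 49) for the vegan diet, 10979 (mouse 9) to 11701 (mouse 18) for all strains and 1 (mouse 1) to 7 (mouse 16) for the interaction. Then followed 17 (mouse 7) to 160 (mouse 2) within C57BL/6J, 1 (mouse 22) to 1131 (mouse 17) within A/J and 0 (mouse 33) to 188 (mouse 34) within DBA/2J. There were also 0 (mouse 53) to 62 (mouse 50) within SJL. Subcutaneous fat had 14589 (mouse 34) to 16130 (mouse 25) for all strains, 0 (mouse 1) to 363 (mouse 22) for the interaction and 0 (mouse 12) to 21 (mouse 13) within C57BL/6J. Further counts were 0 (mouse 18) to 1433 (mouse 22) within A/J, 0 (mouse 34) to 385 (mouse 39) within DBA/2J and 0 (mouse 55) to 31 (mouse 63) within SJL. Visceral fat had 8211 (mouse 40) to 9906 (mouse 24) for all strains, 24 (mouse 13) to 1078 (mouse 59) for the interaction and 167 (mouse 13) to 1133 (mouse 1) within C57BL/6J. Next came 0 (mouse 20) to 436 (mouse 22) within A/J, 0 (mouse 33) to 17 (mouse 40) within DBA/2J and 0 (mouse 54) to 1929 (mouse 49) within SJL. Muscle stayed at 0 for the Mediterranean diet, the vegetarian diet and the vegan diet. Subcutaneous and visceral fat stayed at 0 for all diets, the Mediterranean diet, the vegetarian diet and the vegan diet. Between the depots the count ranged from 16093 (mouse 7) to 16842 (mouse 38).

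What depth limits was not tested apart from the spread between mice: the library totals started at 18.0 M counts, and in simulated data 20.9% of added 1.5-fold and 84.8% of added 4-fold changes between the vegan and American diets were recovered in visceral fat, against 46.3% and 90.9% in liver.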

Other observations

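The scan described here was chosen only after the values of Slc28a1 were seen. In A/J mouse 27 this nucleoside transporter gene was at 0 CPM in liver, 0.544 in muscle, 0.103 in brown fat, 0.196 in subcutaneous fat and 0.089 in visceral fat. In the other 7 A/J libraries it ranged from 14.5 to 49.5, 7.96 to 34.4, 26.2 to 82.7, 32.7 to 123 and 11.4 to 30.9 CPM. The medians of the other strains were 0.0658, 0.284, 0.153, 0.191 and 0.385 CPM. Among 29 mice with all 5 tissues and 17092 genes, 2 mice had a gene beyond the range of their strain by 2-fold in all 5 tissues: mouse 27 with Slc28a1 and SJL mouse 53 with Cish, both lower.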
